A study of Rattus norvegicus with 12 samples.

How the data were processed

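Transcripts of 12 liver samples from Sprague Dawley rats were measured by RNA sequencing in 4 groups of 3 libraries: a normal diet (Control), a normal diet with S-allylmercaptocysteine (Control+SAMC), a high fat diet (HFD) and a high fat diet with S-allylmercaptocysteine (HFD+SAMC). S-allylmercaptocysteine (SAMC) is a water-soluble organosulfur compound found in aged garlic. Groups were taken from the treatment labels and replicate numbers from the sample titles, which run 2, 3 and 4 in the HFD group and 1, 2 and 3 in the others. The labels give no dose, duration, sex or age, and they do not state that the samples come from separate animals. The p-values thus measure the spread between these samples, which may be technical. Pairs of libraries within a group had a chi-square per degree of freedom of 115 to 867. Repeat sequencing of 1 library would give about 1, so these values argue against it, while repeats of the preparation stay open.

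Per the labels' protocols, total RNA was isolated with Trizol, ribosomal RNA was removed with a Ribo-Zero kit, libraries were made with a NEBNext Ultra RNA kit, and paired reads of 150 bp were sequenced on an Illumina HiSeq instrument. Reads were trimmed with Trimmomatic 0.36 and inspected with FastQC, per the submitters' processing notes. The authors aligned reads to the rat genome with HISAT2 and made the deposited count of reads per gene with HTSeq, per the labels' protocols. The genome build, the annotation release and the strand setting of HTSeq are not given in the sources used here. The authors' own differential expression, run with DESeq per the labels' protocols, is not analysed here. The same deposited table holds an RPKM value per gene and library, which equalled the count divided by gene length and library total within a relative difference of 1e-06 for all but 1 of the 40154 genes. For that gene, RGD1562465, the RPKM implied a length of 3377 bp in the 6 Control and HFD+SAMC libraries and 4432 bp, the length listed in the table, in the 6 Control+SAMC and HFD libraries. These libraries are called set 1 and set 2 in the text, since the difference shows that their values were made with different length tables. Each planned comparison of 2 groups sets a library group of 1 set against a group of the other.

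Since the strand setting is not stated, it is unknown whether reads of a gene were told from those of an overlapping or antisense partner. Reads of near-identical copies can also be split or lost in counting per gene, so values of Cyp2b1 and Cyp2b2, the Gsta, Gstm and Ugt1a families, hemoglobin genes, Hsp90aa1, pseudogenes and genes named as like another gene are uncertain. Gene names, types and coordinates are those of the deposited table. Its Entrez numbers matched a reference table of rat genes for 29159 genes, which was used for names only. Coordinates are given without a build, since none is named.

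Total counts per library ranged from 45680738 (Control+SAMC replicate 1) to 61937544 (HFD+SAMC replicate 3). Of 40154 genes, 14180 had no count in any library. The filterByExpr function kept 15916 genes, which held 99.96% of counts, and these were tested in R 4.3.3 with edgeR 4.0.16. Libraries were scaled by the trimmed mean of M-values (TMM), and all 12 entered 1 quasi-likelihood fit with robust dispersion and 8 residual degrees of freedom. The common biological coefficient of variation was 0.299. Planned contrasts were HFD against Control, HFD+SAMC against HFD, Control+SAMC against Control, HFD+SAMC against Control+SAMC, and the interaction of diet and SAMC. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg within each contrast, and the threshold was 0.05. CPM values (counts scaled to a library of 1e+06 counts) use TMM-scaled library sizes and are given as mean ± SD over n = 3 libraries. Log2 fold changes are given ± their standard error (SE).

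For each contrast, 28 gene lists and 15 lists of cell type markers were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 43 lists. The same lists were tested with the correlation estimated from the data and with fry. Some lists share members, so their results are not independent. The p of fry tests whether the genes of a list move, on balance, one way, its mixed p tests change in either direction, and neither compares a list with other genes. Only in Control+SAMC against Control did any planned call hold with an estimated correlation, for 3 lists that are named there. Members past 0.05 were also counted when adjusted over the list alone. Groups, contrasts, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took genes past the threshold with a mean log2 CPM of at least 1, a non-provisional symbol and no overlap between the libraries of the groups compared. From these it named the 10 largest changes each way in the first 3 contrasts and 5 in the others, filled up to 5 by unadjusted p where fewer passed. It added up to 4 list members with the smallest p per list, and the genes of the series title in the first 3 contrasts. Cyp1a1, Cyp1a2, Nqo1 and Hmox1 are not taken from the title but were added as readouts. They are counted among the title genes in the text. A few genes that the rule would name are not reported here. With 3 libraries against 3, chance alone gives no overlap for 10% of genes.

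The test was tested on simulated data drawn from the real means, library sizes and dispersions, with 200 genes changed, 50 at each fold. For HFD against Control (15636 genes) it recovered 2% at 1.5-fold, 32% at 2-fold, 72% at 4-fold and 86% at 8-fold, with 3 false among 99 calls. For HFD+SAMC against HFD (15643 genes) these were 6%, 26%, 66% and 88%, with 4 false among 97. For Control+SAMC against Control (15591 genes) they were 6%, 30%, 70% and 82%, with 4 false among 98. For HFD+SAMC against Control+SAMC (15629 genes) they were 4%, 28%, 64% and 82%, with 4 false among 93. For the interaction (15642 genes) they were 0%, 6%, 46% and 62%, with 4 false among 61. A list of Nrf2 targets raised 1.5-fold in simulated Control+SAMC libraries gave a camera adjusted p of 1.8e-12, and 0 other lists passed. Each gene was drawn independently, so this cannot show how often camera calls lists falsely where genes of a list vary together. Changes under 2-fold were thus mostly beyond the reach of single-gene tests at this replication.

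Alternatives were other scaling factors (RLE, upper quartile, none), DESeq2 1.42.0, limma-voom with quality weights, other low-count filters, fits of the compared groups alone, the replicate number as a block, a minimum log2 fold change of 1, limma-trend on log2 of the deposited RPKM plus a pseudocount of 0.1, 0.5 or 1 with or without a filter at a mean RPKM of 1, and each library left out in turn. Added after the data were seen were fits without Control replicate 2 and HFD+SAMC replicate 3, without pseudogenes and like-named genes, and with the library set as a term. With the set as a term the fit gives the diet effect averaged over SAMC and the SAMC effect averaged over diet, both balanced over the sets. Contrasts within a set, HFD+SAMC against Control and HFD against Control+SAMC, were added for the same reason. No count or RPKM column lacked a sample (0), and no line of the table lacked a gene (0).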

Results

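Liver RNA was measured in 12 libraries, 3 each from rats on a normal diet (Control), a normal diet with SAMC (Control+SAMC), a high fat diet (HFD) and a high fat diet with SAMC (HFD+SAMC). The series concerns fatty liver disease and whether SAMC acts through drug metabolising enzymes and inflammatory pathways. Total counts ranged from 45680738 to 61937544 per library. Albumin (Alb) took from 7.32% of counts in HFD+SAMC replicate 2 to 21.8% in Control replicate 2. Mitochondrially encoded transcripts took from 1.73% in HFD replicate 3 to 5.36% in Control+SAMC replicate 1. Transcripts of the fibrinogen chain Fga were at 3378 to 3822 CPM in Control replicate 2, Control+SAMC replicate 1, HFD replicate 2 and HFD replicate 3, and at 8221 to 18523 CPM in the other 8 libraries. HFD+SAMC replicate 3 held skeletal muscle transcripts such as Acta1 at 440 CPM, against at most 0.135 CPM in the other 11. Control and HFD+SAMC libraries form set 1 and the others set 2 by the gene lengths behind their RPKM. For many of the genes and lists named, values that do not cross the sets or that average over them are therefore given as well. None are given for some lists, among them fibrosis, PPARa targets, cytochromes P450, glutathione S-transferases and acute phase transcripts. For these a set effect stays open.

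HFD against Control asked what the diet changed. The phenobarbital-inducible cytochromes P450 Cyp2b1 and Cyp2b2 rose most among the named genes, from 0.511 ± 0.13 to 15.3 ± 9.5 CPM (SD, n = 3) and from 3.31 ± 0.48 to 87 ± 64 CPM, or 30.1-fold and 26.3-fold. The sulfotransferase Sult1c2 rose 7.53-fold, from 1.99 ± 0.62 to 15 ± 3.8 CPM, and the pantetheinase Vnn1, a gene of the fatty acid response, rose by 1.39 ± 0.23 (SE) on the log2 scale. Acnat2, an acyl-CoA amino acid N-acyltransferase chosen after its values were seen, rose by 2.57 ± 0.30, from 1.04 to 6.22 CPM. Among the genes that fell, Tmem97, a sterol-regulated membrane protein (chromosome 10, 65811455 to 65820538 in the deposited table), changed by −1.94 ± 0.20, from 68.6 ± 21 to 17.8 ± 2 CPM. The membrane protein Prom1 changed by −3.17 ± 0.34, from 49 ± 15 to 5.45 ± 2 CPM. The matrix protein gene Dpt changed by −1.51 ± 0.25, the phospholipase gene Ddhd1 by −1.32 ± 0.21, the acyl-CoA-binding protein gene Dbi by −1.20 ± 0.20 and the palmitoyltransferase gene Zdhhc14 by −1.15 ± 0.16. Hsp90aa1 and the pseudogene Eif4g2-ps1 also passed, higher by 1.71 ± 0.25 and 1.05 ± 0.17, and both differed between the library sets.

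In all, 23 of 15916 genes passed the adjusted p of 0.05 in this comparison (12 higher and 11 lower; edgeR's quasi-likelihood test, Benjamini-Hochberg), and the genes just described had adjusted p from 0.00402 to 0.0483. At an unadjusted p under 0.05 there were 1697 genes, where 795.8 would be called by chance. Cyp2b1, Prom1 and Tmem97 kept their calls whichever library was left out. Without Control replicate 3, Cyp2b2 and Acnat2 had an adjusted p of 0.0511 and the other 8 genes described had 0.0772 (Zdhhc14) to 0.182 (Vnn1). Without HFD replicate 3 those 8 had 0.0589 to 0.192, and without HFD replicate 2 they had 0.0684 to 0.195. Without Control replicate 2, 7 of the 8 missed the threshold, with 0.0668 (Dbi) to 0.118 (Vnn1), and Zdhhc14 kept its call (0.0476). Without HFD replicate 4 it was missed by Ddhd1 (0.0525), Zdhhc14 (0.0546), Vnn1 (0.0578), Eif4g2-ps1 (0.0738) and Dbi (0.0869). Vnn1, Dpt, Ddhd1, Dbi and Eif4g2-ps1, close to the threshold, also missed it without libraries of other groups, with 0.0513 to 0.0945 without Control+SAMC replicate 1 or 2 or HFD+SAMC replicate 2 or 3. Vnn1, Dpt and Dbi missed it without Control+SAMC replicate 3 (0.0554 to 0.0564), and Dpt, Dbi and Eif4g2-ps1 without HFD+SAMC replicate 1 (0.0795 to 0.0915). The count ran from 4 genes without Control replicate 3 to 53 without Control replicate 1. With the diet effect averaged over SAMC, which is balanced over the sets, 67 genes passed and 14 of the 23 were among them. These included Cyp2b1, Cyp2b2, Vnn1, Sult1c2, Acnat2, Tmem97, Prom1, Dpt, Ddhd1, Dbi and Zdhhc14, but not Hsp90aa1 or Eif4g2-ps1.

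Transcripts of cholesterol synthesis and uptake were lower in HFD than in Control for all 26 measured genes, with a median log2 fold change of −1.99. They included the lanosterol demethylase Cyp51 (−2.50 ± 0.42) and the sterol reductase Tm7sf2 (−1.94 ± 0.34). In this list 2 genes passed when adjusted over all genes and 25 when adjusted over the list alone (camera adjusted p = 6.6e-25, and 0.45 with an estimated correlation). Lipogenesis transcripts were lower too, with a median of −0.85 over 27 genes. The stearoyl-CoA desaturase Scd stood at −5.23 ± 1.11, the fatty acid synthase Fasn at −2.46 ± 0.61, the desaturase Fads1 at −1.89 ± 0.43 and the citrate carrier Slc25a1 at −0.92 ± 0.17, with 0 genes past the threshold over all genes and 8 adjusted over the list alone (camera adjusted p = 6.7e-07, and 0.49 with an estimated correlation). Targets of PPARa, the fatty acid receptor, were higher by a median of 0.23 over 50 genes, among them Ehhadh (1.10 ± 0.27), while Cyp4a2 and Cyp4a3 were at −1.11 and −1.07 (camera adjusted p = 0.0016, and 0.55 with an estimated correlation). One member, Vnn1, passed over all genes, and 4 higher and 2 lower passed adjusted over the list alone. Drug-metabolising cytochromes P450 were higher by a median of 0.19 over 30 genes, with Cyp3a62 at 2.97 ± 0.56 and Cyp3a18 at 2.11 ± 0.40, 2 genes past the threshold over all genes and 5 adjusted over the list alone (camera adjusted p = 0.0021, and 0.45 with an estimated correlation). These 4 medians moved with Control replicate 2. Without it they were −0.26 for lipogenesis, −0.99 for cholesterol synthesis, 0.15 for PPARa targets and 0.31 for cytochromes P450 (0.12 without Control replicate 3).

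Inflammasome genes were higher in HFD by a median of 0.31 over 27 genes, led by the sensor Naip6 (1.27 ± 0.26), Il1b (0.96 ± 0.28), Nlrp12 (0.90 ± 0.22) and the channel Panx1 (0.86 ± 0.22). None passed over all genes (0) and 5 did adjusted over the list alone (camera adjusted p = 0.0016, and 0.45 with an estimated correlation). Kupffer cell and macrophage markers were higher by a median of 0.47 over 17 genes, with Aif1 at 1.24 ± 0.31, Lyz2 at 1.28 ± 0.39, Tyrobp at 0.63 ± 0.17 and C1qa at 0.47 ± 0.15 (0 past the threshold over all genes, 4 adjusted over the list alone; camera adjusted p = 5.1e-07, and 0.49 with an estimated correlation). Fibrosis genes were higher by a median of 0.26 over 34 genes, with Col1a2 at 2.27 ± 0.53 (0 over all genes, 3 adjusted over the list alone; camera adjusted p = 0.0024, and 0.49 with an estimated correlation). Acute phase transcripts were lower by a median of −0.30 over 29 genes, with Crp at −0.89 ± 0.20 (0 over all genes, 1 adjusted over the list alone; camera adjusted p = 0.0016, and 0.49 with an estimated correlation). HFD replicates 2 and 3 had mean levels of −0.27 and −0.52 for this list relative to all libraries. With Control replicate 2 and Control+SAMC replicate 1 they make up the 4 libraries with low fibrinogen transcripts. These follow no single group but are unevenly spread, with none in HFD+SAMC. HFD replicate 4, at 0.055, lay within the Control libraries (−0.11 to 0.40). Hepatocyte markers were lower by a median of −0.46 over 12 genes, with Serpina1 at −0.83 and Apoa1 at −0.97 (0 over all genes, 1 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.0097, and 0.49 with an estimated correlation). They missed the threshold without Control replicate 2 (0.0795) or HFD replicate 3 (0.0603), and their median was −0.69 without HFD replicate 4. Erythroid markers were lower by a median of −0.84 (0 over all genes and 0 adjusted over the list alone; camera adjusted p = 0.0066, and 0.49 with an estimated correlation; 0.0838 without Control replicate 3 and 0.0603 without HFD replicate 3). The shares of cell types were not measured. The Kupffer cell median was 0.31 without Control replicate 1 and the fibrosis median 0.16 without HFD replicate 3. None of the genes in the series title passed, nor did the added readouts Nqo1, Cyp1a1, Cyp1a2 and Hmox1. The log2 fold change was 0.87 ± 0.27 for Nlrp3 (adjusted p = 0.274, edgeR's quasi-likelihood test with Benjamini-Hochberg), 0.73 ± 0.34 for Nqo1, 0.22 ± 0.25 for Nfkbia, −0.23 ± 0.15 for Rela, 0.10 ± 0.12 for Nfkb1 and −0.60 ± 0.46 for Ahr. For Nfe2l2 it was 0.07 ± 0.16, for Cyp1a1 1.54 ± 1.40, for Cyp1a2 −0.37 ± 0.23 and for Hmox1 −0.20 ± 0.51, and Nlrp6 had 0 counts in every library. The NF-kB (adjusted p = 0.11), AhR (0.75) and Nrf2 (0.26) lists did not pass camera. In all, 12 lists passed, 9 without HFD replicate 3 and 18 without HFD replicate 4.

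**Figure D1:**
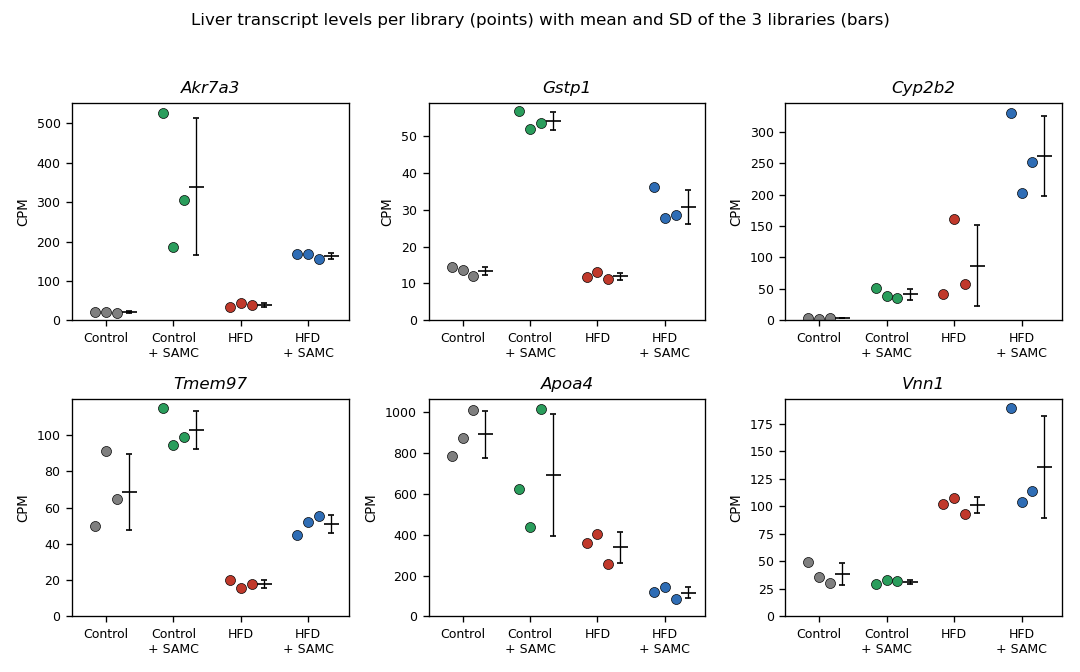
CPM values (linear axes from 0) of 6 transcripts in the 4 groups, with 1 point per library and bars for the mean and SD of 3 libraries. Akr7a3 and Gstp1 were higher in both SAMC groups, Cyp2b2 was higher in HFD and SAMC groups than in Control, Tmem97 was lowest in HFD (mean of 17.8 CPM), and Apoa4 was lowest in HFD+SAMC (mean of 116 CPM).

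HFD+SAMC against HFD asked what SAMC changed on the high fat diet. The aflatoxin aldehyde reductase Akr7a3 (chromosome 5, 157801120 to 157813756), a target of the antioxidant regulator Nrf2, rose 4.26-fold, from 38.4 ± 5.5 to 164 ± 6.8 CPM (SD, n = 3). The glutathione S-transferase Gstp1 (chromosome 1, 219291679 to 219294147) rose 2.57-fold, from 12 ± 0.95 to 30.8 ± 4.7 CPM. Tmem97 rose 2.85-fold, from 17.8 ± 2 to 50.8 ± 5.1 CPM, to below its Control mean of 68.6 CPM. The ubiquitin ligase gene Rnf144b fell from 102 ± 11 to 53 ± 7.8 CPM (log2 −0.95 ± 0.14, SE). Acnat2, again named after its values were seen, fell from 6.22 ± 1.2 to 1.54 ± 0.49 CPM (log2 −2.02 ± 0.29). Next by p, and short of the threshold, were the protease inhibitor gene A2ml1 at −3.09 ± 0.46 (adjusted p = 0.0618), Acsf2 at 1.17 ± 0.19, Gstm1 at 1.46 ± 0.24, Mtmr7 at −2.11 ± 0.35, Hnrnpab at −1.37 ± 0.23 and Apon at −0.98 ± 0.17.

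In this comparison 8 genes passed (3 higher and 5 lower; edgeR's quasi-likelihood test, Benjamini-Hochberg), with adjusted p of 0.00332 for Gstp1, 0.0191 for Tmem97 and 0.0311 for Akr7a3, Rnf144b and Acnat2; 1690 genes had an unadjusted p under 0.05. The remaining 3, named after their values were seen, were LOC100911847, LOC100911991 and LOC103691939, lower by −1.57, −1.77 and −1.48. Only Gstp1 kept its call whichever library was left out. Without HFD+SAMC replicate 3 adjusted p was 0.0677 for Acnat2, 0.0824 for Tmem97, 0.115 for Akr7a3 and 0.171 for Rnf144b. Those 4 genes had 0.132 to 0.150 without HFD replicate 3, 0.121 to 0.271 without HFD+SAMC replicate 2, 0.0624 to 0.166 without HFD replicate 2 and 0.0514 to 0.0664 without Control replicate 3. Without HFD replicate 4, Tmem97, Acnat2 and Akr7a3 had 0.0554, 0.105 and 0.106, and without HFD+SAMC replicate 1 Akr7a3 and Acnat2 had 0.14 and 0.19. Akr7a3, Rnf144b and Acnat2 also missed the threshold without 1 or 2 of the Control+SAMC libraries (up to 0.0596). The count was 1 without HFD+SAMC replicate 3 and 27 without Control replicate 2. With the SAMC effect averaged over diet, 35 genes passed, among them 5 of the 8, namely Akr7a3, Gstp1, Tmem97, Rnf144b and Acnat2.

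Cholesterol synthesis transcripts were higher in HFD+SAMC than in HFD for all 26 genes, with a median of 1.29, Cyp51 at 1.67 ± 0.41 and Tm7sf2 at 1.46 ± 0.33 (0 past the threshold over all genes, 9 adjusted over the list alone; camera adjusted p = 3.4e-14, and 0.66 with an estimated correlation). Nrf2 targets were higher by a median of 0.33 over 28 genes, with 22 above 0. They included Gsta3 (1.64 ± 0.31) and the conjugate exporter Abcc3 (1.60 ± 0.37), with 2 past the threshold over all genes and 5 adjusted over the list alone (camera adjusted p = 1.1e-05, and 0.66 with an estimated correlation). Glutathione S-transferases were higher by a median of 0.17, with Gstt3 at 2.20 ± 0.48 (1 over all genes, 5 adjusted over the list alone; camera adjusted p = 0.0016, and 0.66 with an estimated correlation). Inflammasome genes were lower for 21 of 27 genes, with a median of −0.28, P2rx7 at −0.86 ± 0.23, Il1b at −0.66 and Casp1 at −0.63 ± 0.21 (0 over all genes and 0 adjusted over the list alone; camera adjusted p = 0.0078, and 0.66 with an estimated correlation). Kupffer cell markers were lower by a median of −0.32, with Aif1 at −1.47 ± 0.31 and Adgre1 at −1.14 ± 0.38 (camera adjusted p = 0.0085, and 0.79 with an estimated correlation; 0.0837 without HFD replicate 2 and 0.062 without HFD+SAMC replicate 1), with 0 past the threshold over all genes and 1 adjusted over the list alone. The AhR list was higher by a median of 0.34, with the glucuronosyltransferase Ugt1a6 at 1.38 ± 0.38 (0 over all genes, 2 adjusted over the list alone; camera adjusted p = 0.015, and 0.62 with an estimated correlation; 0.116 without HFD replicate 4). T and NK cell markers were lower by a median of −0.34 (0 over all genes and 0 adjusted over the list alone; camera adjusted p = 0.040, and 0.79 with an estimated correlation; 0.107 without HFD replicate 2, 0.0831 without HFD replicate 3 and 0.0573 without HFD+SAMC replicate 2). Muscle markers passed from HFD+SAMC replicate 3 (camera adjusted p = 0.036, and 0.331 without it). Without HFD replicate 3 the medians were −0.18 for inflammasome genes and −0.21 for Kupffer cell markers (−0.20 without HFD+SAMC replicate 1). For Nrf2 targets the median was 0.21 without HFD+SAMC replicate 2, and for glutathione S-transferases it was 0.28 and 0.075 without HFD replicates 2 and 4 and 0.097 without HFD+SAMC replicate 1.

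Title genes did not pass here either. The log2 fold change was −0.57 ± 0.27 for Nlrp3 (adjusted p = 0.479, edgeR's quasi-likelihood test with Benjamini-Hochberg), −0.37 ± 0.25 for Nfkbia, 0.82 ± 0.23 for Cyp1a2 (adjusted p = 0.269), 1.65 ± 1.28 for Cyp1a1, 0.30 ± 0.34 for Nqo1, 0.48 ± 0.51 for Hmox1 and 0.38 ± 0.46 for Ahr. For Nfe2l2 it was −0.19 ± 0.16, for Nfkb1 0.07 ± 0.12 and for Rela 0.11 ± 0.15. The NF-kB (adjusted p = 0.50) and lipogenesis (0.51) lists did not pass camera. Of the lipid droplet list, which did not pass either (0.33), Hsd17b13 at −0.72 ± 0.13 and Apoa4 at −1.54 were lower and Cidea at 1.10 was higher. In all, 12 lists passed, 7 without HFD replicate 3 and 13 without HFD+SAMC replicate 3. HFD replicates 2 and 3 but no HFD+SAMC library had low fibrinogen transcripts, so that state is mixed into this comparison. Nlrp3 was at 7.11 and 8.26 CPM in HFD replicates 2 and 3 and at 3.67 CPM in HFD replicate 4. In the HFD+SAMC libraries it was at 3.77 to 4.92 CPM. Control replicate 2 and Control+SAMC replicate 1, also low in fibrinogen transcripts, had Nlrp3 at 3.28 and 3.80 CPM. High Nlrp3 thus did not go with low fibrinogen outside the HFD group.

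Control+SAMC against Control asked what SAMC changed on a normal diet. Akr7a3 rose 17.0-fold, from 19.9 ± 2.4 to 340 ± 173 CPM (SD, n = 3), and Gstp1 rose 4.05-fold, from 13.4 ± 1.2 to 54.2 ± 2.5 CPM. Cyp2b2 rose 12.5-fold, from 3.31 ± 0.48 to 41.6 ± 8.9 CPM, and Cyp2b1 10.6-fold, from 0.511 ± 0.13 to 5.4 ± 1.6 CPM. Conjugating enzymes rose as well, with Ugt1a6 up 9.98-fold (10.9 ± 1.7 to 109 ± 52 CPM), Gsta3 by 2.36 ± 0.31 (SE) on the log2 scale and Gstm1 by 1.97 ± 0.25. The conjugate exporter Abcc3 rose by 3.09 ± 0.40, the acyl-CoA synthetase Acsm3 by 2.34 ± 0.35 and the retinal dehydrogenase Aldh1a1 by 1.65 ± 0.26. The glutathione reductase Gsr rose by 0.98 ± 0.15. Rn7sl1, the RNA of the signal recognition particle, was lower by −2.07 ± 0.33 and also differed between the library sets. Below the threshold were Tle3 at −1.0 ± 0.18 (adjusted p = 0.0739), Ddhd1 at −1.05, Tmem125 at −1.58 and H2afv at −0.84.

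In this comparison 19 genes passed (18 higher and 1 lower; edgeR's quasi-likelihood test, Benjamini-Hochberg), with adjusted p of 4.9e-05 for Gstp1, 0.000243 for Akr7a3 and 0.0159 to 0.0415 for the others described; 1557 genes had an unadjusted p under 0.05. Akr7a3 and Gstp1 kept their calls whichever library was left out. The other 10 described lost theirs without any 1 of the Control libraries, with adjusted p of 0.0634 (Gstm1) to 0.112 (Aldh1a1) without replicate 1, 0.0571 (Gstm1) to 0.121 (Acsm3) without replicate 2 and 0.148 (Gstm1) to 0.220 (Gsr) without replicate 3. Acsm3, Aldh1a1, Cyp2b1, Cyp2b2, Gsr and Rn7sl1 also lost theirs without Control+SAMC replicate 1 (0.0731 to 0.108), and all of these but Cyp2b2 without HFD+SAMC replicate 2 (0.0521 to 0.0782). Acsm3, Aldh1a1, Cyp2b1, Gsr and Rn7sl1 each lost theirs without further single libraries too (up to 0.165, for Rn7sl1 without Control+SAMC replicate 2). The count was 3 without Control replicate 1 or 3 and 23 without Control+SAMC replicate 3. With the SAMC effect averaged over diet 12 of the 19 passed, among them Akr7a3, Gstp1, Cyp2b1, Cyp2b2, Ugt1a6, Abcc3, Gsta3, Gstm1, Aldh1a1, Gsr and Mrps27, but not Acsm3 or Rn7sl1.

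Nrf2 targets were higher in Control+SAMC than in Control for 25 of 28 genes, with a median of 0.97, 7 past the threshold over all genes and 16 adjusted over the list alone (camera adjusted p = 3.6e-21, and 0.020 with an estimated correlation). Glutathione S-transferases were higher by a median of 0.64 over 22 genes (3 over all genes, 10 adjusted over the list alone; camera adjusted p = 3.3e-12, and 0.061 with an estimated correlation). Glucuronosyltransferases and sulfotransferases were higher by a median of 0.35 over 28 genes. Among them were Ugt1a7c at 1.80 ± 0.42, Ugt2b17 at 1.51 ± 0.37 and the UDP-glucose dehydrogenase Ugdh at 1.08 ± 0.25. Of this list 1 gene passed over all genes and 5 adjusted over the list alone (camera adjusted p = 2e-06, and 0.020 with an estimated correlation). The AhR list was higher by a median of 0.84 over 10 genes, with Gsta2 at 1.58 ± 0.44, Nqo1 at 1.22 ± 0.35 and Cyp1a1 at 4.41 ± 1.46 (1 over all genes, 4 adjusted over the list alone; camera adjusted p = 4e-05, and 0.020 with an estimated correlation). Ugt1a6, Nqo1 and Gsta2 in this list are also induced through other receptors, and Nqo1 is also in the Nrf2 list. Genes of glutathione and sulfur amino acid metabolism were higher by a median of 0.25 over 38 genes, with Selenbp1 at 2.40 ± 0.57, Gclm at 1.39 ± 0.39 and Gclc at 1.22 ± 0.35 (1 over all genes, 4 adjusted over the list alone; camera adjusted p = 0.0025, and 0.21 with an estimated correlation). Other phase I enzymes were higher by a median of 0.26, with the epoxide hydrolase Ephx1 at 2.50 ± 0.42 (2 over all genes, 5 adjusted over the list alone; camera adjusted p = 0.00017, and 0.38 with an estimated correlation). Cholesterol synthesis transcripts were higher for 24 of 26 genes, with a median of 0.60 (0 over all genes and 0 adjusted over the list alone; camera adjusted p = 3.7e-09, and 0.65 with an estimated correlation), which became 0.21, 1.54 and 0.38 without Control replicates 1, 2 and 3. The median of other phase I enzymes was 0.17 without Control replicate 1, and that of glutathione and sulfur amino acid metabolism was 0.15 without it and 0.062 without Control+SAMC replicate 2. These lists overlap with the Nrf2 list, so they are not separate results. It also holds Gstp1, Gsta3 and Gstm1 of the glutathione S-transferases, Gsr, Gclm and Gclc of glutathione metabolism, Ugdh, and the phase I enzymes Akr7a3 and Ephx1. Ugt1a6 is in both the AhR and the glucuronosyltransferase lists.

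Sinusoidal endothelial markers were lower, with Clec4g at −0.75 ± 0.18 (0 over all genes, 1 adjusted over the list alone; camera adjusted p = 0.030, and 0.51 with an estimated correlation), but at 0.279 without Control replicate 2 and 0.292 without Control+SAMC replicate 1. T and NK cell markers were lower by a median of −0.54 over 15 genes (0 over all genes and 0 adjusted over the list alone; camera adjusted p = 0.011, and 0.73 with an estimated correlation). They had 0.0561 and 0.228 without Control replicates 2 and 3 and 0.490 without Control+SAMC replicate 1, and medians of −0.28, −0.27 and −0.90 without Control replicate 3, Control+SAMC replicate 1 and Control+SAMC replicate 2. B and plasma cell markers were lower by a median of −0.63 over 9 genes (0 over all genes and 0 adjusted over the list alone; camera adjusted p = 0.021, and 0.51 with an estimated correlation; 0.167 and 0.0850 without Control replicates 2 and 3). Of the title genes, Cyp1a1 stood at 0.247 ± 0.37 CPM in Control and 5.51 ± 7.3 CPM in Control+SAMC (adjusted p = 0.365, edgeR's quasi-likelihood test with Benjamini-Hochberg) and Nqo1 had an adjusted p of 0.273. The log2 fold change was 0.57 ± 0.51 for Hmox1, 0.47 ± 0.23 for Cyp1a2, −0.21 for Nfe2l2, −0.20 for Nfkbia, −0.13 for Ahr, −0.12 for Rela, −0.03 for Nlrp3 and −0.01 for Nfkb1. The inflammasome (adjusted p = 0.69), NF-kB (0.73), lipogenesis (0.39) and Kupffer cell (0.88) lists did not pass camera. Fibrosis genes were higher here as well, by a median of 0.24 (camera adjusted p = 0.047). Without Control+SAMC replicate 2 their median was −0.010 (0.407). Like HFD against Control, this comparison sets a group of set 2 against Control of set 1, so a set effect stays open for both. The mean level of fibrosis genes relative to all libraries was −0.20 in Control and 0.021 in HFD+SAMC (set 1). In set 2 it was 0.029 in Control+SAMC and 0.15 in HFD. In all, 14 lists passed, 10 without Control replicate 3 and 17 without Control+SAMC replicate 3.

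HFD+SAMC against Control+SAMC asked what the diet changed under SAMC. Cyp2b1 rose by 3.38 ± 0.42 (SE, n = 3) on the log2 scale, from 5.4 ± 1.6 to 56 ± 12 CPM (SD). Vnn1 rose by 2.11 ± 0.23, from 31.5 ± 1.9 to 136 ± 47 CPM, the lipid droplet gene Cidea by 1.68 ± 0.26, from 10.5 ± 2.4 to 33.5 ± 4.2 CPM, and the deubiquitinase gene Josd2 by 0.83 ± 0.12. The apolipoprotein gene Apoa4 fell from 694 ± 297 to 116 ± 28 CPM (log2 −2.57 ± 0.31) and A2ml1 from 18.6 ± 3.9 to 1.96 ± 0.74 CPM (log2 −3.25 ± 0.46). Eif4g2-ps1 was lower by −1.14 ± 0.17, the opposite of its direction in HFD against Control. Gstp1 was at −0.81 ± 0.13 and did not pass (adjusted p = 0.0527). Here 10 genes passed (4 higher and 6 lower; edgeR's quasi-likelihood test, Benjamini-Hochberg), with adjusted p from 0.00951 (Vnn1) to 0.0442 for those described, and 1732 had an unadjusted p under 0.05. Without Control+SAMC replicate 2 the adjusted p of Vnn1 was 0.0656, and the count was 1 without that library or without HFD+SAMC replicate 3, and 45 without Control replicate 2. The call of Apoa4 ended without any 1 of the HFD+SAMC libraries (0.086, 0.0579 and 0.0881 without replicates 1, 2 and 3). Cyp2b1, Cidea, Josd2, A2ml1 and Eif4g2-ps1 lost theirs without any of those libraries (up to 0.207), without Control+SAMC replicate 1 (0.0654 to 0.117) or 2 (0.113 to 0.149), and without Control replicate 3 (0.0657 to 0.0704). Each of these 5 also lost its call without Control+SAMC replicate 3 or an HFD library (0.0584 to 0.111). Averaged over SAMC, Cyp2b1, Vnn1, Cidea, Josd2 and Apoa4 passed for diet.

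Cholesterol synthesis transcripts were lower in HFD+SAMC than in Control+SAMC for all 26 genes, with a median of −1.43 and Insig1 at −2.67 ± 0.63 (0 over all genes, 18 adjusted over the list alone; camera adjusted p = 4.5e-19, and 0.32 with an estimated correlation). Lipogenesis transcripts were lower by a median of −0.79, with Scd at −6.81 ± 1.20 (0 over all genes, 8 adjusted over the list alone; camera adjusted p = 1.7e-07, and 0.32 with an estimated correlation). Nrf2 targets were lower for 24 of 28 genes, with a median of −0.42 and Akr7a3 at −1.06 ± 0.29 (0 over all genes, 4 adjusted over the list alone; camera adjusted p = 9e-07, and 0.32 with an estimated correlation). Periportal hepatocyte genes were lower by a median of −0.28 (1 over all genes and 1 adjusted over the list alone, Apoa4; camera adjusted p = 0.00042, and 0.32 with an estimated correlation). Glucuronosyltransferases and sulfotransferases passed as lower, with a median of −0.36 but a mean of 0.01 (0 over all genes, 1 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.027, and 0.32 with an estimated correlation; 0.0987 without Control+SAMC replicate 1, 0.0757 without HFD+SAMC replicate 2 and 0.0779 without HFD+SAMC replicate 3). Of the cell type lists, erythroid (median −1.30; camera adjusted p = 0.00021) and hepatocyte markers (−0.29; 0.049) were lower. Kupffer cell (0.27; 0.038), T and NK cell (0.38; 0.027), B and plasma cell (0.55; 0.040), adipocyte (0.38; 0.027) and muscle markers (3.14; 0.027) were higher. With an estimated correlation these 7 had 0.32 to 0.75, and without Control+SAMC replicate 1 none of them passed (0.0584 to 0.694). Their medians also moved, to −0.43 for erythroid, 0.055 for T and NK cell and 0.20 for adipocyte markers without that library, to 0.14 for Kupffer cell and 0.30 for B and plasma cell markers without HFD+SAMC replicate 2, and to 0.85 for muscle and 0.19 for adipocyte markers without HFD+SAMC replicate 3. Without Control+SAMC replicate 2 they were 0.76 for T and NK cell and 0.63 for adipocyte markers, and without replicate 3 the adipocyte median was 0.64. Without Control+SAMC replicate 1 the medians were −0.39 for lipogenesis and −0.25 for Nrf2 targets, and without replicate 2 that of glucuronosyltransferases and sulfotransferases was −0.23. The inflammasome (adjusted p = 0.17), NF-kB (0.17) and AhR (0.068) lists did not pass. In all, 18 lists passed, 7 without Control+SAMC replicate 1 and 19 without HFD replicate 3.

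**Figure D2:**
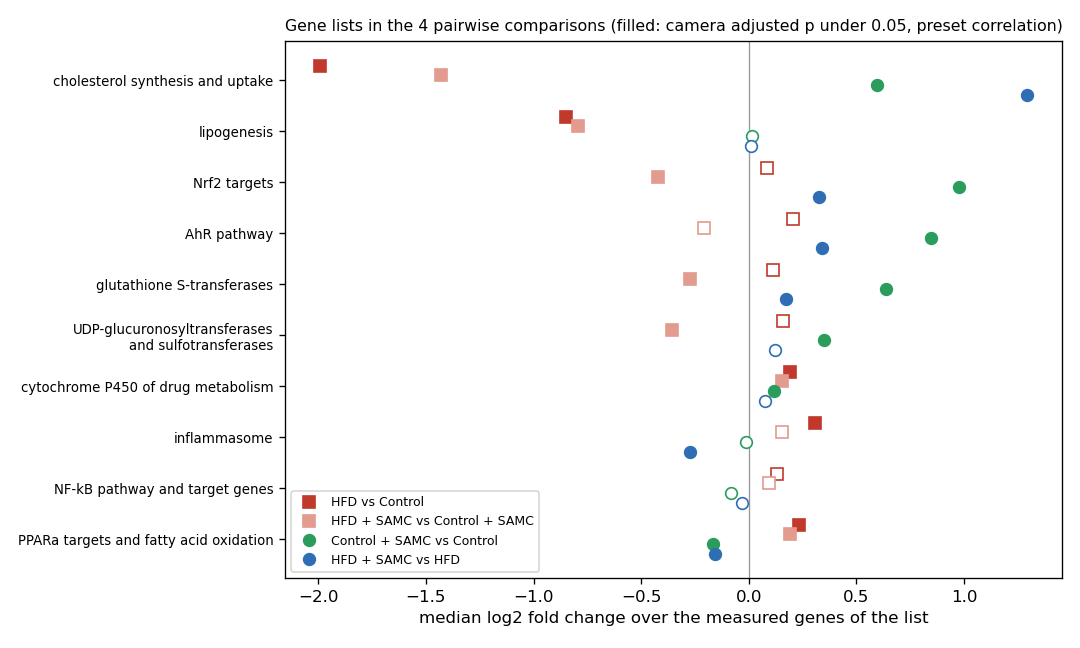
Median log2 fold change (horizontal axis) of 10 gene lists in the 4 comparisons of 2 groups, with filled symbols where camera's adjusted p was under 0.05 at the preset correlation. Cholesterol synthesis transcripts lay at −1.99 in HFD against Control and at 1.29 in HFD+SAMC against HFD, and Nrf2 targets at 0.97 in Control+SAMC against Control and 0.33 in HFD+SAMC against HFD.

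Both library sets can be looked into separately in 2 comparisons that change diet and SAMC together, chosen after the data were seen. Within set 1, HFD+SAMC against Control, Cyp2b1 was higher by 6.79 ± 0.51, Akr7a3 by 3.04 ± 0.31, Gstm1 by 1.92 ± 0.25 and Vnn1 by 1.82 ± 0.23, and Apoa4 was lower by −2.94 ± 0.31, Prom1 by −2.36 ± 0.33 and Ddhd1 by −2.07 ± 0.21 (adjusted p from 0.000705 to 0.0161, edgeR's quasi-likelihood test with Benjamini-Hochberg, 28 genes). Tmem97 was at −0.43 ± 0.19, with an adjusted p of 0.377. Within set 2, HFD against Control+SAMC, Paqr7 was higher by 2.57 ± 0.40 and Vnn1 by 1.68 ± 0.23, while Insig1 was lower by −3.98 ± 0.67, Akr7a3 by −3.15 ± 0.31, Cyp51 by −3.10 ± 0.43, Tmem97 by −2.53 ± 0.20 and Gstm1 by −1.51 ± 0.25 (adjusted p from 0.000207 to 0.0439, 58 genes). Nrf2 targets were higher in the SAMC group of each set, by a median of 0.29 in set 1 (camera adjusted p = 3.3e-06, and 0.23 with an estimated correlation) and with a median of −0.78 for HFD less Control+SAMC in set 2 (4.8e-16, and 0.061). Cholesterol synthesis transcripts were lower in the high fat group of each set, by medians of −0.75 (camera adjusted p = 0.001, and 0.76 with an estimated correlation) and −2.81 (1e-37, and 0.12). In set 1 the mean level of this list relative to all libraries was −0.54, 1.52 and −0.031 in Control replicates 1, 2 and 3. The HFD+SAMC libraries were at −0.44 to 0.071, so only Control replicate 2 lay above all of them. Inflammasome genes passed in set 2 alone, higher in HFD by a median of 0.46 (camera adjusted p = 9.3e-05, and 0.12 with an estimated correlation).

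Averaged over SAMC, the high fat diet raised Cyp2b1 (4.14 ± 0.32, SE), the xenobiotic receptor gene Nr1i3 (2.05 ± 0.34), Vnn1 (1.75 ± 0.16), the progestin receptor Paqr7 (1.65 ± 0.28) and the histidine decarboxylase Hdc (3.97 ± 0.68), and lowered Scd (−6.02 ± 0.82), the sterol sensor Insig1 (−2.95 ± 0.45), Prom1 (−2.35 ± 0.23), Apoa4 (−1.98 ± 0.21) and Tmem97 (−1.48 ± 0.14). Of 67 genes past the threshold 38 were higher and 29 lower (edgeR's quasi-likelihood test, Benjamini-Hochberg). Cholesterol synthesis (median −1.70; 5 over all genes, 25 adjusted over the list alone; camera adjusted p = 1.6e-31, and 0.27 with an estimated correlation) and lipogenesis (median −0.72; 2 over all genes, 10 adjusted over the list alone; 1.9e-10, and 0.27) were lower. The inflammasome list was higher (median 0.24; 0 over all genes, 5 adjusted over the list alone; camera adjusted p = 0.0023, and 0.27 with an estimated correlation), as were the NF-kB list (median 0.15; 0 over all genes and 0 adjusted over the list alone; 0.036, and 0.35) and Kupffer cell markers (median 0.37; 0 over all genes, 6 adjusted over the list alone; 3.5e-06, and 0.35). Averaged over diet, SAMC raised the aldo-keto reductase Akr1b8 22.5-fold (4.49 ± 0.56), Akr7a3 (3.09 ± 0.22), Ugt1a6 (2.35 ± 0.28), Abcc3 (2.35 ± 0.27), Gsta3 (2.00 ± 0.22), Gstm1 (1.71 ± 0.17), Tmem97 (1.05 ± 0.14) and Acsf2 (0.81 ± 0.13), and lowered Tle3 (−0.94 ± 0.13), Ddhd1 (−0.90 ± 0.15) and the endothelial lectin Clec4g (−0.74 ± 0.12). Here 35 genes passed, 26 higher and 9 lower. Nrf2 targets (median 0.52; 8 over all genes, 15 adjusted over the list alone; camera adjusted p = 2e-18, and 0.040 with an estimated correlation) and the AhR list (median 0.70; 1 over all genes, 6 adjusted over the list alone; 2.1e-05, and 0.040) were higher, and cholesterol synthesis transcripts were higher by a median of 0.91 (0 over all genes, 12 adjusted over the list alone; 2e-18, and 0.37). Inflammasome genes were lower by a median of −0.19 (0 over all genes, 1 adjusted over the list alone; camera adjusted p = 0.023, and 0.45 with an estimated correlation). Kupffer cell markers did not pass for SAMC (median −0.07, camera adjusted p = 0.094). Other cell type lists passed for the diet, with hepatocyte (median −0.39; camera adjusted p = 0.0023) and erythroid markers (−1.08; 2.9e-05) lower and T and NK cell (0.39; 0.0075) and adipocyte markers (0.44; 0.024) higher. For SAMC, T and NK cell (−0.50; 0.0012), B and plasma cell (−0.44; 0.022) and endothelial markers (−0.11; 0.037) were lower. With an estimated correlation these 7 results had adjusted p of 0.27 to 0.54.

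Whether SAMC reversed the effects of the diet was asked by setting HFD+SAMC against HFD beside HFD against Control. Of the 23 genes changed by the diet, 4 passed in the opposite direction with SAMC, namely Tmem97 (down, then up) and Acnat2, LOC100911991 and LOC103691939 (up, then down). Independent comparisons would share 0.00377 genes up then down and 0.00207 down then up by chance, but both of these use the HFD libraries. Simulations without any effect gave 0.01 on average but hold almost no calls. Another 100 simulations, chosen after the values were seen, kept the observed difference of Control from the high fat groups without an effect of SAMC. On average 245 genes passed for the diet and 0.03 in the opposite direction for SAMC. A reversal needs a call for SAMC, and these simulations hold almost none, so such a low value was given in advance. Neither kind of simulation thus measures how many of the 4 genes chance would reverse. With the library set as a term Tmem97 and Acnat2 passed for both diet and SAMC, and LOC100911991 and LOC103691939 for neither. LOC100911991 was also higher in Control+SAMC than in Control, by 1.90. Across 15916 genes, which are not independent replicates, the fold changes had a Pearson correlation of −0.44 and a Spearman correlation of −0.40. The shared HFD libraries alone gave a Pearson correlation of −0.495 (−0.521 to −0.453) in 100 simulations without effect, and −0.307 (−0.341 to −0.274) in those with the diet difference kept, whose 245 calls for the diet exceeded the 23 observed. The observed value lay between the 2, so it does not settle whether there was a reversal across genes. The covariance was −0.192, beyond the −0.116 of the simulations by −0.0762, and part of that excess may come from the shared libraries, since 3 HFD libraries cannot be divided into parts of at least 2. The set effect also enters the comparisons with opposite signs. Fold changes had opposite signs for 64.7% of genes, against 66.5% in the simulations.

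The effects of SAMC on each diet, which share no library, had a Pearson correlation of 0.109 and a Spearman correlation of 0.151 across genes. The simulations without effect gave a Pearson correlation of 0.00188 (−0.0366 to 0.0377), but they draw each gene independently. In the real libraries, deviations from the group means correlated between libraries of different groups, from −0.353 to 0.314. The simulated range is thus too narrow to settle whether 0.109 lies beyond chance. The set effect also enters the SAMC effects on each diet with opposite signs, which by itself would lower their correlation. Akr7a3 and Gstp1 rose in both, where 0.00339 genes would be shared by chance, and LOC100911991 passed in opposite directions.

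The interaction asked whether SAMC acted differently on the 2 diets. The transcripts past the threshold were led by Eif4g2-ps1 (−2.18 ± 0.25, SE), Hnrnpab (−2.58 ± 0.32), Hsp90aa1 (−2.47 ± 0.34), Serpina10 (−2.33 ± 0.34) and, upward, Rn7sl1 (3.25 ± 0.46). The interaction is the same comparison as that of the 6 Control and HFD+SAMC libraries (set 1) with the 6 others (set 2), so that library set and interaction cannot be told apart. Rn7sl1 was at 24.5 to 56.2 CPM in set 1 and 6.17 to 15.9 CPM in set 2, Hsp90aa1 at 2.85 to 5.99 and 7.02 to 13.4 CPM, Eif4g2-ps1 at 3.65 to 5.15 and 9.01 to 12.2 CPM, and Fam111a at 0.0224 to 0.147 and 0.348 to 215 CPM. Snap25, named after its values were seen, was at 0 to 0.0154 and 0.222 to 0.739 CPM. In all, 23 genes passed (3 up and 20 down; edgeR's quasi-likelihood test, Benjamini-Hochberg; adjusted p from 0.00611 to 0.0393 for those named by the rule), and 1180 had an unadjusted p under 0.05. Of these, 22 had no overlap between the 6 libraries of each set, and 0 passed between the groups within a set (4 at an unadjusted p under 0.05), where 28 and 58 other genes did. Eif4g2-ps1 and Hnrnpab kept their calls whichever library was left out, while Hsp90aa1 had 0.0516 without Control replicate 2, 0.0531 without HFD replicate 3 and 0.0712, 0.0721 and 0.0542 without HFD+SAMC replicates 1, 2 and 3. Without any 1 of these HFD+SAMC libraries Rn7sl1, Serpina10 and Fam111a missed the threshold too (up to 0.178). Fam111a kept its call only without Control+SAMC replicate 3 and lost it without any other library (up to 0.182, without Control replicate 2). Serpina10 also missed it without Control replicates 2 or 3, Control+SAMC replicates 2 or 3, or HFD replicates 3 or 4 (0.0562 to 0.0955). Rn7sl1 also missed it without Control replicates 2 or 3, Control+SAMC replicate 2 or HFD replicate 4 (0.0615 to 0.0789). The count was 7 without HFD+SAMC replicate 1 and 19 without Control replicate 1. Of the lists, 7 passed, among them Nrf2 targets, with 22 of 28 genes below 0 and a median of −0.64, or −0.42 without HFD replicate 4 (0 over all genes, 9 adjusted over the list alone; camera adjusted p = 1.8e-06, and 0.55 with an estimated correlation). Of its members Akr7a3 stood at −2.00 ± 0.41 (adjusted p = 0.11) and Gclm at −1.80. Fibrosis genes stood at a median of −0.35 (camera adjusted p = 0.013, and 0.169 without Control+SAMC replicate 2). Glucuronosyltransferases and sulfotransferases stood at a median of −0.55, with Ugt1a6 at −1.94 ± 0.53 (0 over all genes, 6 adjusted over the list alone; camera adjusted p = 0.0038, and 0.23 with an estimated correlation).

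**Figure D3:**
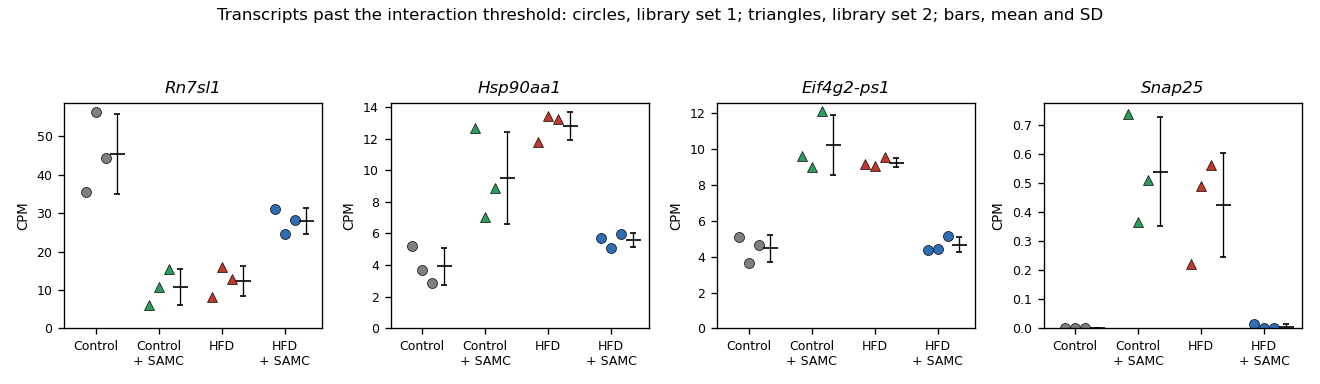
CPM values (linear axes from 0) of 4 transcripts past the interaction threshold, with 1 point per library, circles for library set 1, triangles for set 2, and bars for the mean and SD of 3 libraries. Rn7sl1 was higher in set 1 (24.5 to 56.2 CPM, against 6.17 to 15.9 CPM), and the other 3 were higher in set 2.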

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

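Chosen only after the results were seen were the tests of library sets, of pseudogenes and of muscle transcripts, and the fits within sets or with the set as a term; the tests without the most abundant genes and of other splits of the samples were chosen before.

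The interaction contrast passed the threshold for 23 genes and 7 lists (edgeR's quasi-likelihood test with Benjamini-Hochberg, and camera), led by Eif4g2-ps1, Hsp90aa1, Hnrnpab and Rn7sl1. This contrast also parts the 6 libraries of set 1 from the 6 of set 2, whose RPKM rest on different gene lengths. Pseudogenes and genes named as like another made up 9 of the 23 (39.1%), against 10.9% of tested genes (one-sided Fisher's exact p = 0.000407), and the 406 annotated pseudogenes were higher in set 2 by a median log2 of 0.28, against −0.05 and −0.01 within the sets (camera p = 1.1e-10, and 0.000298 with an estimated correlation). These values are consistent with processing of reads that differed between the sets, such as the sharing of reads between copies. A response to SAMC that depends on diet cannot be told apart from it, since 0 of the 23 genes passed between groups within a set (4 at an unadjusted p under 0.05) and the design puts set and interaction in the same contrast.

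Of 100 regroupings of the samples for the interaction, 4 gave as many genes as the real one (23, with 95 the highest of the others). This share lies under 0.05, but 3 of the 4 were other groupings with more genes. Chance is therefore not excluded for the gene count, nor is a set effect. The 3 others with as many, at 26, 61 and 95 genes, put Control replicate 2, Control+SAMC replicate 1, HFD replicate 2 and HFD replicate 3 on the same side, which points to a structure of the samples that the groups do not follow; these are the libraries with low fibrinogen transcripts. For the 7 interaction lists, 82 of 100 regroupings gave as many, up to 22, and chance cannot be excluded.

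Nrf2 targets were higher in Control+SAMC than in Control and lower transcripts of cholesterol synthesis marked HFD against Control, and each of these comparisons crosses the sets. Within both sets the lists still passed in the direction of SAMC (larger camera adjusted p = 3.31e-06) and of the diet (larger adjusted p = 0.00104). With an estimated correlation none of the 4 passed (0.23 and 0.061 for Nrf2 targets and 0.76 and 0.12 for cholesterol synthesis in sets 1 and 2). For the cholesterol list a set effect would run in opposite directions in HFD against Control and HFD+SAMC against Control+SAMC. Its mean level relative to all libraries was −0.54 to 1.52 in Control and −1.80 to −0.96 in HFD. It was 1.02 to 1.44 in Control+SAMC and −0.44 to 0.071 in HFD+SAMC. The list was thus lower on the high fat diet without overlap in both of these comparisons, which argues against a set effect as the whole cause. A part played by it stays open. Within set 1, Control and HFD+SAMC overlapped, and Control replicate 2 alone lay above all HFD+SAMC libraries. The call of this list within set 1 thus adds little. For Nrf2 targets, Akr7a3 passed within both sets (adjusted p = 0.00185 and 0.0013) and the list passed for SAMC averaged over diet (0.040 with an estimated correlation), which argues against a set effect as the whole cause. The 10 most abundant genes were Alb, Tf, C3, Apoe, COX1, Apob, Serpina1, Fga, Pzp and Serpina3n. Without them the median of the Nrf2 list was 0.9874 against 0.9746. TMM scaling already trims the most abundant genes, so leaving them out could hardly move this median. The test therefore cannot decide whether a few genes taking most of the counts played a part. Direct effects of SAMC on Nrf2 and of dietary sterols on cholesterol synthesis may explain the shifts of both lists. Neither sterol content nor Nrf2 activity was measured, and differences in handling or feeding state of the animals stay open.

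In HFD+SAMC replicate 3, 9 of 9 skeletal muscle markers were at least 10 times above the highest other library, among them Acta1 at 440, Myh1 at 188 and Ckm at 162 CPM, while 0 of 3 smooth muscle markers were. The skeletal markers took 0.109% of its counts. None of these markers (0) was above the libraries of the other groups in both other HFD+SAMC libraries, which argues against an effect of SAMC on a high fat diet. Muscle tissue in the sample is a candidate source.

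The 6 libraries of 2 groups can be split in 10 ways, too few for a share under 0.05. For HFD against Control, 1 split gave 23 or more genes (the real one; highest other 0), and 5 gave 12 or more lists (highest other 13). For HFD+SAMC against HFD, 1 split gave 8 or more genes (highest other 0) and 2 gave 12 or more lists (highest other 12). For Control+SAMC against Control, 2 splits gave 19 or more genes (highest other 62) and 4 gave 14 or more lists (highest other 20). The split with 62 genes set Control replicate 2 and Control+SAMC replicates 1 and 2 against the other 3, which points to a structure of the samples. For HFD+SAMC against Control+SAMC, 1 split gave 10 or more genes (highest other 1) and 2 gave 18 or more lists (highest other 20).

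For the effects averaged over the other factor, 100 regroupings of the 12 libraries were drawn. Only the real one gave as many genes for diet (1 of 100, with 67 genes and 3 in the highest other). The same held for SAMC (1 of 100, with 35 genes and 4 in the highest other). Chance can thus be excluded only as a random placing of all 12 labels at once. Each regrouping moves the differences of diet, SAMC and library set into the spread within groups, which can lower its calls. Neither effect was thus tested alone, and both contrasts were chosen after the data were seen. For the list counts chance cannot be excluded. There 11 regroupings gave as many as the 16 lists for diet (highest other 21) and 21 as many as the 15 for SAMC (highest other 23).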

How the results depend on the processing

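Leaving out Control replicate 2 with HFD+SAMC replicate 3, leaving out pseudogenes and like-named genes, and taking the library set as a term were chosen after seeing the data; the other alternatives were planned. Where no cause is given, the cause was not tested.

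In HFD against Control 23 genes passed. The count was 310 with DESeq2 (181 higher, 129 lower), 144 with limma-voom, 136 with no scaling factors (123 higher, 13 lower), 67 with the library set as a term, 14 without pseudogenes and like-named genes, 7 without the 2 doubted libraries and 4 with only the compared groups in the fit. On RPKM it was 116, 122 and 125 with a filter at pseudocounts 0.1, 0.5 and 1, and 38 and 71 with no filter at 0.1 and 1. Leaving out single libraries gave 4 (Control replicate 3) to 53 (Control replicate 1). In HFD+SAMC against HFD, with 8 genes, it was 234 with DESeq2, 39 with voom, 35 with the set as a term, 23 with only the compared groups, 19 with no low-count filter, and on RPKM 13 (0.1 with filter), 5 (0.1, no filter) and 17 (1, no filter), with 1 (without HFD+SAMC replicate 3) to 27 (without Control replicate 2) for single libraries.

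In Control+SAMC against Control, with 19 genes, the count was 203 with DESeq2, 40 with voom, 35 with the set as a term, 6 with the replicate block, 5 with only the compared groups, 4 without the 2 doubted libraries, and 5 and 7 on unfiltered RPKM at pseudocounts 0.5 and 1, with 3 (without Control replicate 1 or 3) to 23 (without Control+SAMC replicate 3) for single libraries. In HFD+SAMC against Control+SAMC, with 10 genes, it was 248 with DESeq2, 67 with the set as a term, 44 with only the compared groups, 33 with voom, 21 with no low-count filter, 17 on filtered RPKM at pseudocount 1, 5 with no scaling factors, 3 without pseudogenes and like-named genes, 2 with the replicate block and 2 without the 2 doubted libraries, with 1 (without Control+SAMC replicate 2 or HFD+SAMC replicate 3) to 45 (without Control replicate 2) for single libraries. For the interaction, with 23 genes, it was 119 with DESeq2, 51 with voom, 41, 38 and 43 on unfiltered RPKM at pseudocounts 0.1, 0.5 and 1, 10 without pseudogenes and like-named genes, 9 with the replicate block and 6 without the 2 doubted libraries, with 7 (without HFD+SAMC replicate 1) to 19 (without Control replicate 1) for single libraries. Without pseudogenes and like-named genes fewer genes were tested, and without libraries fewer samples. The genes called in each comparison of 2 groups were all called by DESeq2 as well.

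With an estimated correlation camera called 0, 0, 3, 0 and 0 lists in the 5 contrasts in the order above, and fry 1, 0, 4, 0 and 0, against 12, 12, 14, 18 and 7. Fry's 4 were Nrf2 targets, glutathione S-transferases, the AhR list, and glucuronosyltransferases with sulfotransferases. Without single libraries the counts of lists were 9 (HFD replicate 3) to 18 (HFD replicate 4), 7 (HFD replicate 3) to 13 (HFD+SAMC replicate 3), 10 (Control replicate 3) to 17 (Control+SAMC replicate 3), 7 (Control+SAMC replicate 1) to 19 (HFD replicate 3), and 5 to 11 (Control replicate 2). Mitochondrially encoded transcripts, called lower in HFD than in Control and higher in HFD+SAMC than in HFD, had the opposite direction without HFD replicate 3 (camera adjusted p = 0.485 and 0.5), and without single libraries their adjusted p began at 2.64e-05 and 2.3e-05 (both without HFD replicate 2).

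The Pearson correlation of the diet effect and the SAMC effect on that diet was −0.738 over called genes alone and −0.609 with the replicate block, and −0.558 (without HFD replicate 4) to −0.318 (without Control replicate 1). The count of genes reversed was 12 at an adjusted p under 0.10 and 7 with the block, and 0 (without HFD+SAMC replicate 3) to 7 (without Control replicate 2). The correlation of the SAMC effects was 0.223 with the filter at 1 CPM, 0.0797 with the block, and −0.216, the opposite sign, over called genes alone, and 0.0451 (without Control replicate 2) to 0.148 (without Control replicate 1).

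Of 54 calls of named genes, 6 stayed past the threshold under the alternatives of scaling, test, groups in the fit, replicate block and single libraries: Akr7a3, Gstp1 and LOC100911991 in Control+SAMC against Control, Gstp1 in HFD+SAMC against HFD, Eif4g2-ps1 in the interaction and LOC100911991 in HFD against Control. With the library set as a term LOC100911991 passed neither for diet (adjusted p = 0.928) nor for SAMC (0.905). Of their 1018 values under alternatives 663 stayed past the threshold, 355 did not and 0 reversed. With no scaling factors the median of all genes shifted by 0.29, −0.02, 0.13, 0.14 and −0.15 in the 5 contrasts, and the sign of title genes near 0 changed with it. In Control+SAMC against Control these were Ahr (0.0629), Nfkb1 (0.112, and 0.00601 with upper-quartile factors), Nlrp3 (0.0962) and Rela (0.00606), and in HFD against Control Hmox1 (0.0328) and Rela (0.0456). All of these values lay below the shift of all genes under the same factors (0.02 for the upper quartile), so that relative to it no sign changed. With voom Nlrp3 was at 0.00821 in Control+SAMC against Control. Leaving out single libraries also turned signs. In Control+SAMC against Control the range was −0.51 to 0.48 for Ahr, −0.14 to 0.0596 for Nfkb1, −0.54 to 0.00485 for Nfkbia and −0.12 to 0.0780 for Nlrp3, and in HFD against Control −0.98 to 0.00434 for Ahr, −0.60 to 0.20 for Hmox1 and −0.0425 to 0.19 for Nfe2l2. None of these genes was called. The replicate numbers did not pair the samples, since correlations of same-numbered libraries ran from −0.22 to 0.25 and 1 of 12 libraries matched its own number best. At the depth of these libraries the self-test recovered 26% to 32% of 2-fold changes between 2 groups and 6% for the interaction.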

Other observations

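No test in this part was chosen after the result was seen, since values alone are given.

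Fibrinogen and other acute phase transcripts fell into separate clusters of libraries that followed no single group, though the low cluster held no HFD+SAMC library. Fgb was at 3297 to 3929 CPM and Fgg at 2958 to 3254 CPM in Control replicate 2, Control+SAMC replicate 1, HFD replicate 2 and HFD replicate 3, and at 6425 to 14052 and 5924 to 16198 CPM in the other 8. Serpina3n was at 1792 to 3401 against 6431 to 22842 CPM, and the metallothionein Mt2A at 32.7 to 437 against 654 to 2013 CPM. The first principal component, with 18.1% of the variance, set the same 4 libraries apart.

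The labels give no sex. The P450 gene Cyp2c12, typical of female rat liver, was at 2561 to 4571 CPM in all 12 libraries, Cyp2c11, typical of male rat liver, at 0 to 0.386 CPM, and the Y-linked Ddx3y at 0.399 to 1.41 CPM.

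Several transcripts varied widely within groups. Hdc ranged from 7.04 to 157 CPM in HFD and from 1.21 to 1.98 CPM in Control. Across the 12 libraries the sulfotransferase Sult2a2 ranged from 1.19 to 139 CPM, and the clock genes Noct, Per2 and Arntl from 0.636 to 61.2, 4.06 to 97.0 and 1.27 to 28.3 CPM, while the labels give no time of sampling.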
